A study of Danio rerio with 12 samples.

How the data were processed

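Droplet-based single cell sequencing of the 3′ ends of transcripts had been done on telencephalon cells dissociated with papain, in 12 libraries of 4 pooled animals each. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422 and counted with Cell Ranger 4.0.0 against GRCz11, and the deposited values are UMI counts per gene and barcode (25107 genes, 120827 barcodes). Which barcodes the authors had left out before they deposited the counts is not recorded. The annotation in hand was of another assembly, so it served for gene names and for the order of genes only, and no coordinate is given.

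Group, genotype, time and treatment came from the labels. The library set and the read layout (2 layouts, 3 library sets) came from the labels where they give them. The layout of wildtype intact replicates 2 and 3 is not stated; it was assigned from the order of the samples and the numbers in their names.

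Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which left out 1036 barcodes for their genes and 8314 for their mitochondrial share. Scrublet (as in scanpy 1.11.5) was run per library and its automatic calls were left out. They numbered 71, under 0.1% of cells in 11 of 12 libraries, so the caller did not find the doublets that loading would give (about 0.8% per 1000 cells), and an alternative that removes the cells with the highest scores was added. Counts were normalized per cell and logged, and 2000 variable genes, 40 principal components and 15 neighbours (seed 1) were clustered by Leiden (leidenalg 0.10.2) at resolution 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

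Clusters were named from fixed lists of cell type markers, a marker counting where at least 10% of the cells had it at a log2 fold of at least 1, and a name needing at least 3 markers. Further naming rules were chosen only after the clusters had been seen, before any gene was tested. They left unnamed a cluster with flt3 and ccl19a.1, of dendritic cell type (509 cells, 0.130 to 1.28% per library), and a cluster with genes of both microglia and oligodendrocytes (95 cells, 0.620% of the mutant 3 dpi library). They also dealt with cycling cells. Unnamed clusters held 12.0 to 28.4% of the cells per library and entered no comparison. Names end in "-like" because no sorted reference was at hand.

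UMI counts were summed per class and library, with at least 20 cells per sum. Genes were filtered with filterByExpr, scaled by TMM and tested with quasi-likelihood F tests in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons of single groups used all 12 libraries, with a mean per group and a term for read layout, which leaves 3 residual degrees of freedom. Their log2 fold changes are adjusted for that term and can differ from the ratio of pooled CPM. Genotype over the 3 times used the 6 libraries sequenced alike, with terms for time and genotype. The fits, filters, gene lists and the rule for named genes were chosen before the data were examined. DESeq2 1.42.0 served as the second tool.

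Gene lists (28 tested per comparison) were tested with camera at the preset correlation of 0.01 and again with a correlation estimated from the data. No list passed with the estimated correlation in any of the 11 planned comparisons, where 3 to 11 passed with the preset one. CPM values were computed here from the deposited counts. Values of single libraries were scaled with TMM, except those of the targeted genes, their paralogs and the summed oligodendrocyte markers. Values pooled over a group and given beside UMI counts were not scaled with TMM. Genes with 0 UMIs in one group are given as at least N-fold, with a floor of 3 counts over that group, and genes with 1 to 3 UMIs with a 95% counting interval of the ratio. These bounds cover counting error only, not the spread between animals.

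The rule for named genes took, per comparison of microglia-like cells, the 12 highest and 12 lowest log2 fold changes past the threshold with a mean of at least 50 CPM, leaving out clone-style names where more than 5 genes passed, and up to 4 members per list with the smallest adjusted p. In other classes it took the 5 highest and 5 lowest. grna, grnb and tardbp were always named. Genes past it are marked as named after their values were seen.

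The tests were checked on simulated counts drawn with the means, library sizes and spread of these libraries. In microglia-like cells, wildtype 3 dpi against intact found 14% of genes raised 2-fold, 60% of those raised 4-fold and 98% of those raised 16-fold, with 20 false genes among 118 called (16.95%). Lipoamide found 2, 20 and 100%, TDP-43 found 0, 12 and 80%, and genotype over 3 times found 42, 100 and 100%, with 13 false genes among 174 (7.47%). The shares of false genes were 17.07% for lipoamide (14 of 82) and 13.79% for TDP-43 (8 of 58), and 4.1 to 12.5% in the other classes. The aim was 5%. Of genes lowered 4-fold the same comparisons found 24, 14, 8 and 80%, so decreases were harder to call. Small changes are thus mostly out of reach in comparisons that rest on 1 library.

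The alternatives tried were the second tool and its size factors, no filter on low counts, no term for read layout, library set in its place, a replicate block, doublets kept, stricter cells (1000 UMIs and 500 genes), resolution 2, and each library left out. Added after the data were seen were removal of the highest doublet scores, the mixed cluster added to microglia-like cells, a fit without the 2 libraries with the fewest microglia-like cells, injury averaged over both genotypes, genes called in all 4 classes left out, and the 3 dpi interaction. Shares of cells were given with exact intervals and no test was made. A permutation test cannot reach 0.05 with 1 library in a group, and a model that pools the spread over groups was not run.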

Results

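Single cells of the adult zebrafish telencephalon were profiled by droplet sequencing of the 3′ ends of transcripts, before and after a brain lesion, in wildtype fish and in fish mutant for both progranulin genes, grna and grnb. The animals were 3 to 5 months old, and each of the 12 libraries pooled 4 of them. They fell into 8 groups. Wildtype fish were intact (3 libraries) or at 3 or 7 days post injury (dpi, 1 library each), and mutants were likewise intact or at 3 or 7 dpi (1 each). Further groups were mutant at 7 dpi kept in water with lipoamide (2), and wildtype at 7 dpi injected with cleaved TDP-43 (2). Lipoamide is a small molecule studied for its action on stress granules, and TDP-43 is an RNA-binding protein that aggregates in several neurodegenerative diseases. Each library held between 27552414 and 52202375 UMIs. The 6 libraries with 1 sample of each genotype at each time held 12365 to 15984 barcodes with medians of 1237 to 1484 UMIs. The 6 others held 4331 to 7860 barcodes with medians of 4316.5 to 4710.5. After filtering 112408 cells remained, of which 1516 were microglia-like. Groups with 1 library have no spread of their own and were assumed to vary like the replicated groups. In comparisons over all 12 libraries the p-values rest on the spread between pools of animals and between library sets together. The replicates of wildtype intact and of lipoamide lay in different sets. Of the wildtype intact libraries only replicate 1 lay in the set of the intact mutant and of the injured libraries without treatment. Fits without it compare intact wildtype with those between library sets. For genotype over the 3 times the p-values rest on how far the genotype difference disagrees between those times.

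Both targeted genes were measured first. Over all cells, grnb (ENSDARG00000025081) stood at 1.79 to 2.77 CPM (UMI counts scaled to a common library total) in the 5 mutant libraries and at 13.5 to 17.3 in the 7 wildtype libraries. Every mutant library thus lay below every wildtype library. grna overlapped between the genotypes over all cells, at 2.33 to 11.9 CPM in the mutants and 4.92 to 25.5 in wildtype. In microglia-like cells grna (ENSDARG00000004954), the targeted progranulin gene with the higher level in these cells, stood at 226 to 307 CPM in the mutants and at 297 to 815 in wildtype. The log2 difference over the 3 paired times was −0.85 ± 0.28 for grna (SE; 3 libraries per genotype, adjusted p = 0.267, edgeR) and −1.62 ± 0.35 for grnb (adjusted p = 0.0638). tardbp (ENSDARG00000040031), which encodes TDP-43, stood at 0.13 ± 0.23 (adjusted p = 0.923). The short progranulin paralogs varied more than either. grn1 in microglia-like cells ranged from 5.90 to 5500 CPM over the wildtype libraries. Counts came from 3′ tags, and a tag outside the altered part of a gene says nothing about the mutation, so a remaining grna signal does not test the genotype.

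**Figure D1:**
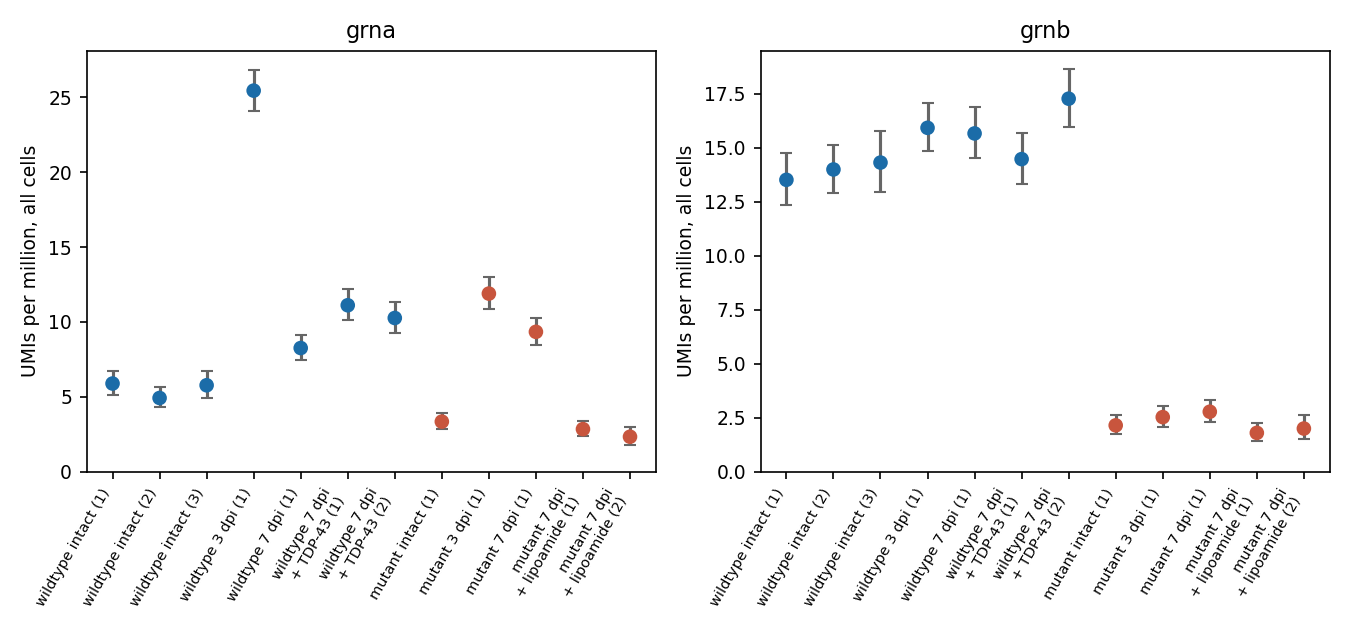
CPM of grna and grnb over all cells of each library (y axis) for the 12 libraries (x axis; wildtype in blue, mutant in red, replicate in brackets), with 95% Poisson intervals that cover counting error only. All 5 mutant libraries lie at or under 2.77 for grnb, and all 7 wildtype libraries at or above 13.5.

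Microglia-like cells, the resident immune cells of the brain, were counted as a share of the cells kept. They made up 0.928% of cells in wildtype intact replicate 1 (95% exact Clopper-Pearson interval 0.762 to 1.12%), 0.508% in replicate 2 and 0.662% in replicate 3. At 3 dpi the share was 1.96% in wildtype (1.73 to 2.199%) and 2.04% in mutant (1.82 to 2.27%), against 0.774% in the intact mutant (0.631 to 0.940%). At 7 dpi it was 1.44% in wildtype (1.25 to 1.66%) and 2.22% in mutant (1.97 to 2.50%). With lipoamide the mutant libraries at 7 dpi held 0.615% (0.438 to 0.840%) and 0.573% (0.360 to 0.867%). With cleaved TDP-43 the wildtype libraries held 1.40% (1.11 to 1.74%) and 0.964% (0.721 to 1.26%). T or NK lymphocyte-like cells ranged from 0.744 to 1.94% in the libraries without TDP-43 and reached 3.01 and 2.67% in those injected with it. Ependymoglia-like cells, the radial glia of the zebrafish forebrain, were 17.6% of the mutant library at 7 dpi and 11.9% of the wildtype one. A permutation test of shares cannot reach 0.05 with 1 library in a group. The lipoamide and TDP-43 libraries belong to the deeper set, in which unnamed clusters also took a smaller share (12.0 to 16.4% against 21.5 to 28.4%).

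**Figure D2:**
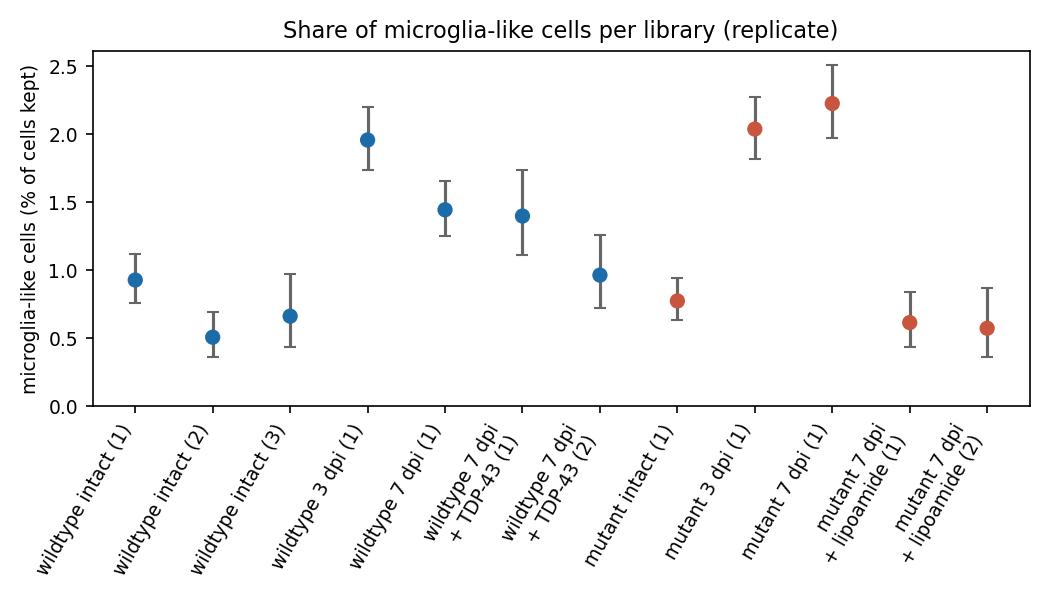
Share of microglia-like cells among the cells kept (y axis, percent) in each of the 12 libraries (x axis; wildtype in blue, mutant in red, replicate in brackets), with 95% exact Clopper-Pearson intervals. The injured libraries without treatment reach 1.44 to 2.22% and the intact ones 0.508 to 0.928%.

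Wildtype microglia-like cells were first compared between 3 dpi and the intact brain, to ask which genes they switch on early after the lesion. The chemokine gene ccl34b.8 (ENSDARG00000093098) rose by 7.24 ± 0.84 on the log2 scale (SE; 1 library against 3, adjusted p = 0.00539, edgeR), from 2.73 to 283 CPM, a ratio with a 95% counting interval of 28.5 to 856. The transferrin gene tfa was at least 61.1-fold higher at 3 dpi, though 51.6% of its 415 UMIs lay in 1 cell. Chemokine, interferon, lysosomal and complement lists stood on the higher side as groups. In the inflammatory list 17 of 29 members lay above 0 (1 passed over all genes and 6 adjusted over the list alone, camera adjusted p = 0.00121, adjusted p = 0.383 with an estimated correlation). Among them were socs3b, a feedback inhibitor of cytokine signalling, at 3.93 ± 0.72 (adjusted p = 0.114) and cxcl8b.1, a chemokine that attracts neutrophils, at 4.11 ± 0.83 (adjusted p = 0.167). The interferon list had 11 of 14 members above 0 (0 over all genes, 3 adjusted over the list alone, camera adjusted p = 0.000528, adjusted p = 0.316 with an estimated correlation). The guanylate-binding protein gene gbp1 stood at 1.99 ± 0.52 and the antiviral GTPase gene mxc at 2.38 ± 0.76. Of the lysosomal list 32 of 47 members lay above 0 (0 over all genes, 1 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.546 with an estimated correlation). ctsba, which encodes cathepsin B, led it at 1.48 ± 0.32 (adjusted p = 0.177). Orthologs of mammalian disease-associated microglia genes had 18 of 26 members above 0 (0 over all genes, 2 adjusted over the list alone, camera adjusted p = 0.00520, adjusted p = 0.316 with an estimated correlation). Complement genes had 6 of 10 (0 over all genes, 1 adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.498 with an estimated correlation). c1qb, a chain of the complement starter C1q, stood at 1.19 ± 0.43.

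Other groups of wildtype microglia-like genes at 3 dpi lay lower. Cell cycle genes had 3 of 32 members above 0 (0 over all genes, 2 lower adjusted over the list alone, camera adjusted p = 4.19e-12, adjusted p = 0.383 with an estimated correlation). Immediate early and heat shock genes had 12 of 44 (0 over all genes, 2 lower adjusted over the list alone, camera adjusted p = 0.000261, adjusted p = 0.316 with an estimated correlation). The small heat shock gene hspb1 stood at −2.10 ± 0.50 and the co-chaperone gene dnajb1b at −1.40 ± 0.30. The lipid droplet list, which holds the perilipins and lipases the study's title points to, had 3 of 14 members above 0 (0 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.350, adjusted p = 0.825 with an estimated correlation). Its acyl-CoA synthetase gene acsl4b stood at −1.01 ± 0.37 (adjusted p = 0.870). Antigen presentation genes (14 of 25 above 0, camera adjusted p = 0.0257, adjusted p = 0.763 with an estimated correlation, pointing down without wildtype intact replicate 1 at adjusted p = 0.982) and ribosomal protein genes (62 of 80 above 0, camera adjusted p = 0.0137, adjusted p = 0.825 with an estimated correlation) lay higher. Erythrocyte markers lay lower (0 of 6 above 0, camera adjusted p = 0.00577, adjusted p = 0.512 with an estimated correlation). Oligodendrocyte markers, which microglia do not express, were higher with them. Of these 5 of 5 lay above 0 and 3 passed adjusted over the list alone (camera adjusted p = 1.13e-10, adjusted p = 0.316 with an estimated correlation). Their summed level was 574 CPM at 3 dpi against 131 in wildtype intact replicate 1. In all, 7 of 6602 genes passed, each higher at 3 dpi (278 at an unadjusted p under 0.05, DESeq2 called 15). The remaining 5, named after their values were seen, were si:dkey-7i4.24 (at least 168-fold higher), zgc:174904, zgc:193725, CABZ01073795.1 and a gene with only a clone-style name (at least 141-fold higher, 954 UMIs in 10 cells). The count was 28 without wildtype intact replicate 1, 11 without replicate 3 and 11 without either lipoamide replicate. It was 15 and 18 without TDP-43 replicate 1 or 2.

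By 7 dpi wildtype microglia-like cells differed from intact ones in fewer genes. The only gene that passed was f13a1a.1 (ENSDARG00000045453), a coagulation factor XIII A chain gene, at least 605-fold higher (adjusted p = 0.000294, edgeR; 115 genes at an unadjusted p under 0.05, DESeq2 called 3). It had UMIs in 4 of 196 cells and 1388 of its 2043 UMIs in 1 of them. Cholesterol biosynthesis genes had 8 of 9 members above 0 (0 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.00194, adjusted p = 0.537 with an estimated correlation). The sterol demethylase gene cyp51 stood at 2.40 ± 0.94, fdps at 1.56 ± 0.74 and hmgcs1, which encodes the synthase that starts the pathway, at 0.90 ± 0.52, each with an adjusted p of 1. Antigen presentation genes lay lower, with 6 of 25 above 0 (camera adjusted p = 0.0206, adjusted p = 0.642 with an estimated correlation). Cell cycle genes did too, with 2 of 32 above 0 (0 over all genes, 1 lower adjusted over the list alone, camera adjusted p = 1.98e-16, adjusted p = 0.537 with an estimated correlation). Markers of oligodendrocytes (camera adjusted p = 3.05e-07, adjusted p = 0.537 with an estimated correlation) and of neurons (15 of 19 above 0, camera adjusted p = 0.00194, adjusted p = 0.642 with an estimated correlation) were higher in the same library. The count of 1 became 0 with the highest doublet scores out and 2 with no read layout covariate. It became 16 without wildtype intact replicate 1, and 2 and 4 without TDP-43 replicate 1 or 2.

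Injury was then followed in the mutants. At 3 dpi mutant microglia-like cells held 144 UMIs of ccl34b.8 where the intact mutant had 0, at least 11.0-fold more (adjusted p = 0.630, edgeR). They held 71 UMIs of the related chemokine gene ccl34a.4 against 1 (42.1 against 2.58 CPM, interval of the ratio 2.84 to 654). The inflammatory list as a whole lay higher (22 of 29 above 0; 0 over all genes, 2 adjusted over the list alone, camera adjusted p = 0.000182, adjusted p = 0.460 with an estimated correlation). So did complement (8 of 10 above 0, camera adjusted p = 0.01001, adjusted p = 0.654 with an estimated correlation). Its member c7b, a gene of the membrane attack pathway, had 98 UMIs against 2 (interval of the ratio 3.04 to 94.4). Cholesterol biosynthesis lay higher (8 of 9 above 0, camera adjusted p = 0.00208, adjusted p = 0.631 with an estimated correlation), and cyp51 had 43 UMIs against 2 (interval of the ratio 1.29 to 42.2). Iron and heme genes had 12 of 20 members above 0 (camera adjusted p = 0.0224, adjusted p = 0.631 with an estimated correlation), the ferritin-like gene fthl31 standing at 1.89 ± 0.55. In all, 1 gene passed, f13a1a.1 (at least 260-fold higher, 3320 of 3394 UMIs in 1 cell; 62 genes at an unadjusted p under 0.05, DESeq2 called 1). The count became 0 with strict cells and 0 with the highest doublet scores out.

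At 7 dpi the mutant cells again stood apart from the intact mutant in groups of genes rather than single ones. Inflammatory genes had 23 of 29 members above 0 (0 over all genes, 1 adjusted over the list alone, camera adjusted p = 7.98e-07, adjusted p = 0.236 with an estimated correlation), and ccl34a.4 had 112 UMIs against 1 (interval of the ratio 5.65 to 1280). Iron and heme genes had 18 of 20 (0 over all genes, 2 adjusted over the list alone, camera adjusted p = 1.31e-06, adjusted p = 0.236 with an estimated correlation). fthl31 stood at 2.92 ± 0.56 and hmox1a, the heme oxygenase gene, at 1.59 ± 0.60. All 9 measured cholesterol biosynthesis genes lay above 0 (camera adjusted p = 0.000329, adjusted p = 0.356 with an estimated correlation), with hmgcs1 at 1.39 ± 0.68. So did 36 of 47 lysosomal genes (camera adjusted p = 0.0108, adjusted p = 0.520 with an estimated correlation). The lipid droplet list had a median of 0.007, a mean of 0.769 and a camera adjusted p of 0.635 (adjusted p = 0.850 with an estimated correlation). Neuron markers were lower in the same library (1 of 19 above 0, camera adjusted p = 7.98e-07, adjusted p = 0.356 with an estimated correlation). No gene passed by edgeR (0 of 6602; 97 at an unadjusted p under 0.05) or by DESeq2 (0), and 10 passed with no filter on low counts.

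The genotypes were compared at each time, to ask how loss of progranulin changes microglia at rest and after injury. Intact mutant cells differed in 2 genes of the major histocompatibility complex (MHC), in opposite directions. mhc2b (ENSDARG00000104635), a class II gene, had 118 UMIs against 1 in the 3 wildtype libraries (304 against 1.37 CPM, interval of the ratio 39.2 to 8860, adjusted p = 0.00953, edgeR). mhc1uba (ENSDARG00000075963), a class I gene, had 1 against 684 (interval of the ratio 6.97e-05 to 0.0154, adjusted p = 0.000304). The complement gene c7b was lower by 4.81 (−4.81 ± 0.73, 2 UMIs against 80, interval of the ratio 0.00561 to 0.176, adjusted p = 0.0336) and gng10, a G protein gamma subunit gene, by 4.08 (−4.08 ± 0.63, adjusted p = 0.0336). Antigen presentation genes as a list had 15 of 25 members above 0 (camera adjusted p = 0.983, adjusted p = 0.995 with an estimated correlation). Ribosomal protein genes had 0 of 80 members above 0 (camera adjusted p = 1.97e-17, adjusted p = 0.746 with an estimated correlation) and inflammatory genes 8 of 29 (camera adjusted p = 0.0463, adjusted p = 0.746 with an estimated correlation). In all, 3 genes were higher and 3 lower (271 at an unadjusted p under 0.05, DESeq2 called 12), the others being zgc:103700 and si:dkey-7i4.24. The 6 calls became 20 without wildtype intact replicate 1, and 14 and 19 without TDP-43 replicate 1 or 2.

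At 3 dpi mutant microglia-like cells had no mhc1uba (0 UMIs against 1095, at least 372-fold lower, adjusted p = 5.75e-05, edgeR) and again expressed mhc2b (at least 111-fold higher, adjusted p = 0.00796). loxl2b, a lysyl oxidase gene, had 1 UMI against 93 (interval of the ratio 0.000265 to 0.0603, adjusted p = 0.0488). Genes of immune activation lay lower in the mutant as groups. Inflammatory genes had 9 of 29 members above 0 (0 over all genes, 1 lower adjusted over the list alone, camera adjusted p = 0.00680, adjusted p = 0.583 with an estimated correlation), with cxcl8b.1 at −3.99 ± 0.85 (adjusted p = 0.230). Interferon genes had 3 of 14 (camera adjusted p = 0.00680, adjusted p = 0.583 with an estimated correlation), with mxc at −2.86 ± 0.83. Complement genes had 3 of 10 (camera adjusted p = 0.00769, adjusted p = 0.609 with an estimated correlation). Antigen presentation genes had 7 of 25 (1 lower over all genes, 2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00399, adjusted p = 0.656 with an estimated correlation). Oligodendrocyte markers were lower with them, at 155 CPM against 574 (0 of 5 above 0, camera adjusted p = 9.68e-06, adjusted p = 0.609 with an estimated correlation). That direction turned when the 95 unnamed cells of the mutant library with genes of both cell types were added, which brought it to 2970 CPM. In all, 5 genes were higher and 5 lower (198 at an unadjusted p under 0.05, DESeq2 called 5), among them tfa lower and f13a1a.1 higher, both with over 50% of their UMIs in 1 cell. The 10 calls became 5 with no read layout covariate, 26 and 21 without wildtype intact replicate 1 or 2, and 22 and 24 without TDP-43 replicate 1 or 2.

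The genotypes were then compared at 7 dpi, where inflammatory and lysosomal genes lay higher in the mutant as groups. Lysosomal genes had 39 of 47 members above 0 (0 over all genes, 1 adjusted over the list alone, camera adjusted p = 0.000558, adjusted p = 0.460 with an estimated correlation). ctss2.2, a cathepsin S gene, stood at 4.47 ± 0.99 (adjusted p = 0.212) and ctsba at 1.41 ± 0.41. Inflammatory genes had 19 of 29 (camera adjusted p = 0.000635, adjusted p = 0.460 with an estimated correlation). Iron and heme genes had 16 of 20 (camera adjusted p = 0.00708, adjusted p = 0.460 with an estimated correlation) and homeostatic microglia genes 21 of 24 (camera adjusted p = 0.0197, adjusted p = 0.648 with an estimated correlation). The apolipoprotein E gene apoeb (ENSDARG00000040295) stood at 1.32 ± 0.30 (adjusted p = 0.255). Antigen presentation genes had 20 of 25 above 0 (camera adjusted p = 0.110, adjusted p = 0.656 with an estimated correlation) and complement genes 5 of 10 (camera adjusted p = 0.702, adjusted p = 0.901 with an estimated correlation). Interferon genes had 7 of 14 (camera adjusted p = 0.669, adjusted p = 0.818 with an estimated correlation). Neuron markers had 0 of 19 above 0 (camera adjusted p = 9.16e-06, adjusted p = 0.460 with an estimated correlation). In all, 4 genes were higher and 2 lower (217 at an unadjusted p under 0.05, DESeq2 called 11). mhc2b (at least 51.0-fold), ms4a17a.9, si:dkey-7i4.24 and zgc:103700 were higher, and mhc1uba (at least 356-fold) and f13a1a.1 lower. The 6 calls became 2 with the highest doublet scores out, 22 and 15 without wildtype intact replicate 1 or 2, and 17 and 24 without TDP-43 replicate 1 or 2.

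Whether injury acted differently in the genotypes at 7 dpi was tested as an interaction. The wildtype intact libraries lay in different library sets, and only replicate 1 shared that of the other libraries in this test. The interaction thus mixes genotype with library set. Cell cycle genes had 32 of 32 members above 0, that is a higher injury effect in the mutant (camera adjusted p = 1.82e-13, adjusted p = 0.479 with an estimated correlation). In wildtype these genes had been lower at 7 dpi than in that mixed baseline. Inflammatory genes had 26 of 29 (0 over all genes, 3 adjusted over the list alone, camera adjusted p = 5.43e-06, adjusted p = 0.306 with an estimated correlation) and lysosomal genes 39 of 47 (camera adjusted p = 0.0183, adjusted p = 0.637 with an estimated correlation). Ribosomal protein genes had 74 of 80 (camera adjusted p = 0.000576, adjusted p = 0.821 with an estimated correlation). Markers of other cell types lay on the other side, those of neurons with 1 of 19 above 0 (camera adjusted p = 3.31e-09, adjusted p = 0.367 with an estimated correlation) and those of oligodendrocytes with 1 of 5 (camera adjusted p = 0.0119, adjusted p = 0.637 with an estimated correlation). The chemokine gene ccl35.2 stood at 2.77 ± 0.69, ctss2.2 at 4.71 ± 1.23, fthl31 at 3.63 ± 0.71 (adjusted p = 0.862) and c7b at 4.87 ± 0.92 (adjusted p = 0.862). No single gene passed by edgeR (0 of 6602; 128 at an unadjusted p under 0.05) or by DESeq2 (0), while 9 did with no filter on low counts and 4 without wildtype intact replicate 1.

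The 3 times together gave a genotype comparison of 3 mutant against 3 wildtype libraries sequenced alike, with 1 library per genotype at each time. Its spread is the disagreement of the genotype difference between the 3 times, not that of replicates. Antigen presentation genes changed in both directions, 3 higher and 2 lower over all genes (5 and 4 adjusted over the list alone, 14 of 26 above 0, camera adjusted p = 0.998, adjusted p = 0.999 with an estimated correlation). mhc2b was at least 199-fold higher in the mutant (708 UMIs against 0, adjusted p = 6.90e-05, edgeR). The class I gene mhc1zba (ENSDARG00000036588) rose by 3.58 ± 0.22 (adjusted p = 3.59e-05) and the class II gene mhc2a by 1.43 ± 0.14 (adjusted p = 0.000789). mhc1uba had 1 UMI against 2012 (interval of the ratio 1.06e-05 to 0.00233, adjusted p = 6.06e-06) and mhc2dab fell by 2.23 (−2.23 ± 0.23, adjusted p = 0.000789). The list of cholesterol efflux and lipoprotein genes did not pass (6 of 12 above 0; 1 higher over all genes and 1 adjusted over the list alone, camera adjusted p = 0.0879, adjusted p = 0.818 with an estimated correlation). Its member apoeb, the main lipid carrier that microglia release, rose by 0.98 ± 0.13 (adjusted p = 0.00430), from 5213 to 6748 CPM (scaled with TMM) in wildtype to 10400 to 13500 in the mutant. g0s2 (ENSDARG00000078859), an inhibitor of triglyceride lipase found on lipid droplets, rose by 0.80 ± 0.15 (adjusted p = 0.0354). A pair of annexin genes and a complement gene were lower. anxa1a (ENSDARG00000026726), a gene of the resolution of inflammation, fell to −4.08 ± 0.35 (adjusted p = 0.000201), anxa2a to −1.99 ± 0.25 (adjusted p = 0.00290) and c1qb to −1.03 ± 0.21 (adjusted p = 0.0457). Most wildtype UMIs of the annexin genes lay in the 3 dpi library, 374 of 412 for anxa1a and 223 of 307 for anxa2a. They came from 25 and 44 of its 276 cells. The complement list had 3 of 9 members above 0 (camera adjusted p = 0.0879, adjusted p = 0.818 with an estimated correlation). Not all of these held between the lipoamide-treated mutant and the TDP-43-injected wildtype libraries, where 77 of the 93 genes with UMIs there kept their direction. mhc2b had 0 UMIs in all 4 of them, mhc1zba stood at means of 333 and 691 CPM, and anxa1a at 125 and 70.6 CPM. mhc1uba stayed at 0 to 2.31 CPM in all 5 mutant libraries and at 640 to 2351 in all 7 wildtype ones.

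Further genes that were higher in mutant microglia-like cells over the 3 times were the sodium channel subunit gene scn4bb (5.84 ± 0.47), the adhesion gene mpzl2b (4.38 ± 0.64), the progranulin paralog grn2 (4.16 ± 0.52), the inflammatory caspase gene caspb (3.17 ± 0.43) and the stress gene nupr1b (2.70 ± 0.32). So were the haemoglobin gene hbaa1 (2.65 ± 0.18, with UMIs in 97.1% of the mutant 3 dpi cells, where free RNA from erythrocytes was not tested), the connexin gene cx32.2 (2.03 ± 0.35), hp, which encodes haptoglobin (1.87 ± 0.25), cdkn1ca (1.52 ± 0.30) and iscub (1.44 ± 0.24). Those lower were aste1a (−3.74 ± 0.41), the NF-κB pathway kinase gene map3k14a (−2.77 ± 0.26), gng10 (−2.75 ± 0.22), the retinol carrier gene rbp4 (−2.68 ± 0.34), glb1l (−2.45 ± 0.24), tppp (−2.29 ± 0.38), the cytokine receptor gene il21r.1 (−1.91 ± 0.24) and the poly(A)-binding protein gene pabpc1b (−1.57 ± 0.27). Of the 421 wildtype UMIs of tppp, 360 lay in the 3 dpi library, 163 of them in 1 cell. The antiviral gene mxc (−2.90 ± 0.36), the glutathione transferase gene gsta.1 (−2.04 ± 0.27) and the heat shock gene hsp70l (−0.81 ± 0.12) were lower as well. Of these grn2, caspb, mxc and hsp70l ran the other way between the lipoamide-treated mutant and the TDP-43-injected wildtype libraries, grn2 at means of 21.2 and 646 CPM and caspb at 17.1 and 189 CPM. In TDP-43 replicate 1 the 246 UMIs of grn2 lay in 3 of 80 cells. In the lipid droplet list 10 of 14 members lay above 0 (1 higher over all genes, 2 adjusted over the list alone, camera adjusted p = 0.178, adjusted p = 0.818 with an estimated correlation). pnpla2, the triglyceride lipase gene, stood at 1.08 ± 0.30 (adjusted p = 0.163). In the RNA granule list, which holds TDP-43 and its partners, 1 of 35 genes was lower over all genes (camera adjusted p = 0.596, adjusted p = 0.894 with an estimated correlation). Ribosomal protein genes lay lower (3 of 80 above 0; 0 over all genes, 38 lower adjusted over the list alone, camera adjusted p = 5.33e-08, adjusted p = 0.818 with an estimated correlation). So did the radial glia injury list (6 of 28 above 0; 2 lower over all genes, 10 adjusted over the list alone, camera adjusted p = 3.51e-09, adjusted p = 0.722 with an estimated correlation). Erythrocyte markers were higher (4 of 6 above 0, camera adjusted p = 0.000257, adjusted p = 0.722 with an estimated correlation), oligodendrocyte markers lower (1 of 5 above 0, camera adjusted p = 7.05e-05, adjusted p = 0.818 with an estimated correlation). The latter pointed up with the mixed cluster added (adjusted p = 0.665). In all, 46 genes were higher and 52 lower of 8016 (823 at an unadjusted p under 0.05, DESeq2 called 76). Of these 98 genes, 5 had most of their UMIs in 1 cell of the library where their count was highest. Named after their values were seen, they included il13 (117 of 117 UMIs) and si:dkey-21e2.8 (48 of 48) in mutant 3 dpi. The others were il4 (75 of 75) in mutant 7 dpi, and kpna2 (51 of 62) and si:ch211-69g19.2 (11 of 19) in wildtype 3 dpi. Of the genes tested 21 passed in the same direction in all 4 classes tested, among them mhc1uba, mhc1zba, hbaa1 and loxl2b. The 98 calls became 65 with the mixed cluster added, 151 without the intact pair, 31 without the 3 dpi pair and 56 without the 7 dpi pair.

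**Figure D3:**
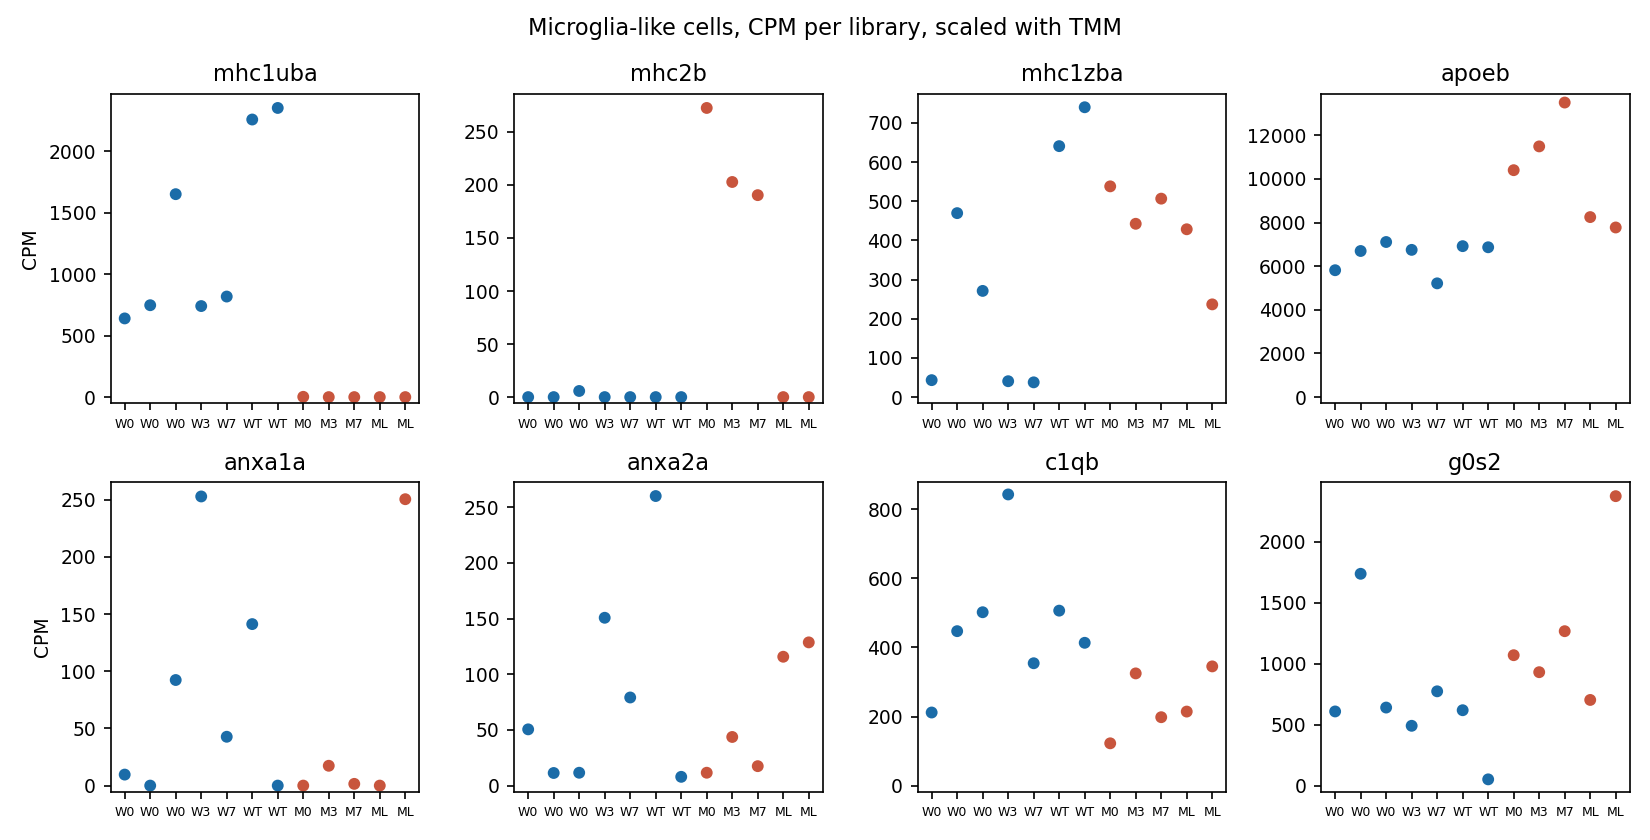
CPM scaled with TMM (y axis) of 8 genes in the summed microglia-like cells of each library (x axis: W wildtype in blue, M mutant in red; 0 intact, 3 and 7 dpi, T cleaved TDP-43, L lipoamide; 1 point per library). apoeb lies at 10400 to 13500 in the 3 mutant libraries without treatment, and at 7774 to 8250 in those with lipoamide.

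Lipoamide was added to the water of injured mutants, and its libraries at 7 dpi were compared with the untreated mutant. Among the genes that passed was a neuropeptide gene. cort, which encodes cortistatin, stood at 6.37 ± 0.90 (2 libraries against 1, adjusted p = 0.0404, edgeR), but 89 of the 90 UMIs in replicate 1 came from 1 cell. The unnamed gene CR759843.2 was at least 13.8-fold lower (0 UMIs against 158, adjusted p = 0.0404). Iron and heme genes lay lower with lipoamide (3 of 20 above 0; 0 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.909 with an estimated correlation), with hmox1a at −1.68 ± 0.60 (242 against 1015 CPM pooled) and fthl31 at −1.63 ± 0.49 (64.8 against 279 CPM). Immediate early and heat shock genes lay higher (30 of 44 above 0; 0 over all genes, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.909 with an estimated correlation). The early response genes stood on that side, btg2 at 1.65 ± 0.37, dusp1 at 1.48 ± 0.43 and jun at 1.17 ± 0.37, the chaperone gene hsp70.1 at −1.60 ± 0.41. Ribosomal protein genes had 69 of 80 above 0 (camera adjusted p = 6.67e-05, adjusted p = 0.942 with an estimated correlation). The lipid droplet list had 9 of 14 members above 0 (0 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.526, adjusted p = 0.942 with an estimated correlation). apoeb stood at −0.59 ± 0.27 (adjusted p = 0.987). The homeostatic list had a median of 0.177 and a mean of −0.037, and its test pointed down (camera adjusted p = 0.812, adjusted p = 0.942 with an estimated correlation). In all, 1 gene was higher and 1 lower (320 at an unadjusted p under 0.05, DESeq2 called 5). The 2 calls became 0 without either lipoamide replicate, with strict cells, with the highest doublet scores out and with no read layout covariate. They became 7 with library set as covariate and 58 with no filter on low counts. They became 9, 6 and 0 without wildtype intact replicate 1, 2 or 3, and 11 and 22 without TDP-43 replicate 1 or 2.

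Cleaved TDP-43 was injected into injured wildtype brains, and microglia-like cells at 7 dpi were compared with injured cells that had no injection. Inflammatory genes lay higher as a group, and 25 of 29 members were above 0 (0 over all genes, 5 adjusted over the list alone, camera adjusted p = 0.000331, adjusted p = 0.661 with an estimated correlation). The chemokine gene cxcl18b had 43 UMIs against 1 (interval of the ratio 7.70 to 1830, adjusted p = 0.837, edgeR) and ccl35.2 stood at 2.45 ± 0.59 (298.8 against 111.7 CPM pooled, adjusted p = 0.948). Antigen presentation genes had 22 of 25 above 0 (camera adjusted p = 0.0164, adjusted p = 0.661 with an estimated correlation), with mhc1zba at 4.54 ± 1.25 (605 against 36.4 CPM). The wildtype intact libraries, which had no injection, held 202 CPM of mhc1zba when pooled, so its level varied without TDP-43 too. Lysosomal genes had 34 of 47 (camera adjusted p = 0.0380, adjusted p = 0.661 with an estimated correlation), with ctsba at 1.98 ± 0.47 (1609 against 767 CPM) and the asparagine protease gene lgmn at 1.71 ± 0.59 (894 against 454 CPM). The interferon-induced gene ifi45 stood at 5.77 ± 1.08 (110 UMIs against 19, 140.5 against 23.1 CPM, adjusted p = 0.573). These fitted values are adjusted for read layout, the pooled CPM are not, and in all 5 genes the CPM differed less. Without TDP-43, ifi45 and cxcl18b were also higher in the lipoamide libraries than in the untreated mutant. There ifi45 stood at 73.2 against 13.3 CPM pooled and cxcl18b at 245 against 8.14. Those libraries too lay in other library sets than their control. The lipid droplet list lay at a camera adjusted p of 0.871 (adjusted p = 0.920 with an estimated correlation). Neuron markers were lower (5 of 19 above 0, camera adjusted p = 0.00187, adjusted p = 0.661 with an estimated correlation) and ependymoglia markers higher (15 of 15 above 0, camera adjusted p = 0.000943, adjusted p = 0.661 with an estimated correlation), the latter pointing down without the read layout (adjusted p = 0.849). No gene passed by edgeR (0 of 6602; 316 at an unadjusted p under 0.05) or by DESeq2 (0). The TDP-43 libraries and the uninjected library lay in different library sets, and 21 genes passed with library set as covariate, 64 with no filter on low counts and 2 with no read layout covariate. The counts were 7 and 1 without wildtype intact replicate 1 or 2, 12 without TDP-43 replicate 2 and 3 without the 2 libraries with the fewest microglia-like cells.

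Effects in microglia-like cells were set against each other across the 6602 genes, which are not independent replicates. The mutant and the TDP-43 effects at 7 dpi share the wildtype 7 dpi library, and their log2 fold changes correlated at 0.287, against 0.377 (SD 0.019) in 30 simulations with no effect. Their covariance was 0.591 against 0.489 simulated, a difference of 0.103. The lipoamide effect and the mutant effect share the mutant 7 dpi library with opposite sign and correlated at −0.142, against −0.395 simulated. They had covariances of −0.212 and −0.407 (difference 0.195). Injury at 7 dpi in wildtype and in mutant shares no library, and the 2 effects correlated at −0.141, against −0.003 simulated. That value became −0.03 without wildtype intact replicate 1 and −0.024 with no filter on low counts. The one for lipoamide became −0.05 without lipoamide replicate 1 and −0.268 with no filter on low counts. The one for TDP-43 became 0.463 with no read layout covariate and 0.464 without the 2 libraries with the fewest microglia-like cells. In the latter fit only the TDP-43 libraries keep the second layout, so the layout term drops out there too. The simulations were run with that term only, so their 0.377 is no reference for these fits. Without wildtype intact replicate 3 the TDP-43 value fell to 0.192. No gene passed in both effects of any pair, where the simulations gave 0.270, 0 and 0.130 shared genes. The TDP-43 effect and mutant injury at 7 dpi had no gene past the threshold at all. For their pairs the lack of shared genes was thus fixed beforehand and says nothing about likeness.

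Ependymoglia-like cells, the stem cells of the zebrafish forebrain, were compared between 3 dpi and the intact brain. The membrane-binding annexin gene anxa2a (ENSDARG00000003216) rose by 2.89 ± 0.16 (1 library against 3, adjusted p = 0.00111, edgeR), hbegfa (ENSDARG00000075121), a growth factor of the EGF family, by 2.73 ± 0.18 (adjusted p = 0.00182). clu, an extracellular chaperone, rose by 2.08 ± 0.24 (adjusted p = 0.0332), vmp1, an autophagy gene, by 1.88 ± 0.20 (adjusted p = 0.0266) and elovl1b, a fatty acid elongase, by 1.43 ± 0.18 (adjusted p = 0.0441). Interferon-induced genes were among the others, named after their values were seen. isg15 rose by 3.97 ± 0.28 and ifi46 by 2.86, together with mvp (2.76), nppc (3.74) and stm (7.35). In all, 21 of 15198 genes passed, each higher (1294 at an unadjusted p under 0.05, DESeq2 called 70). At 7 dpi 0 passed by edgeR (1028 at an unadjusted p under 0.05, DESeq2 called 9). The 21 became 239, 53 and 7 without wildtype intact replicate 1, 2 or 3, 6 without either lipoamide replicate and 8 without either TDP-43 replicate. The 0 at 7 dpi became 131 without wildtype intact replicate 1.

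**Figure D4:**
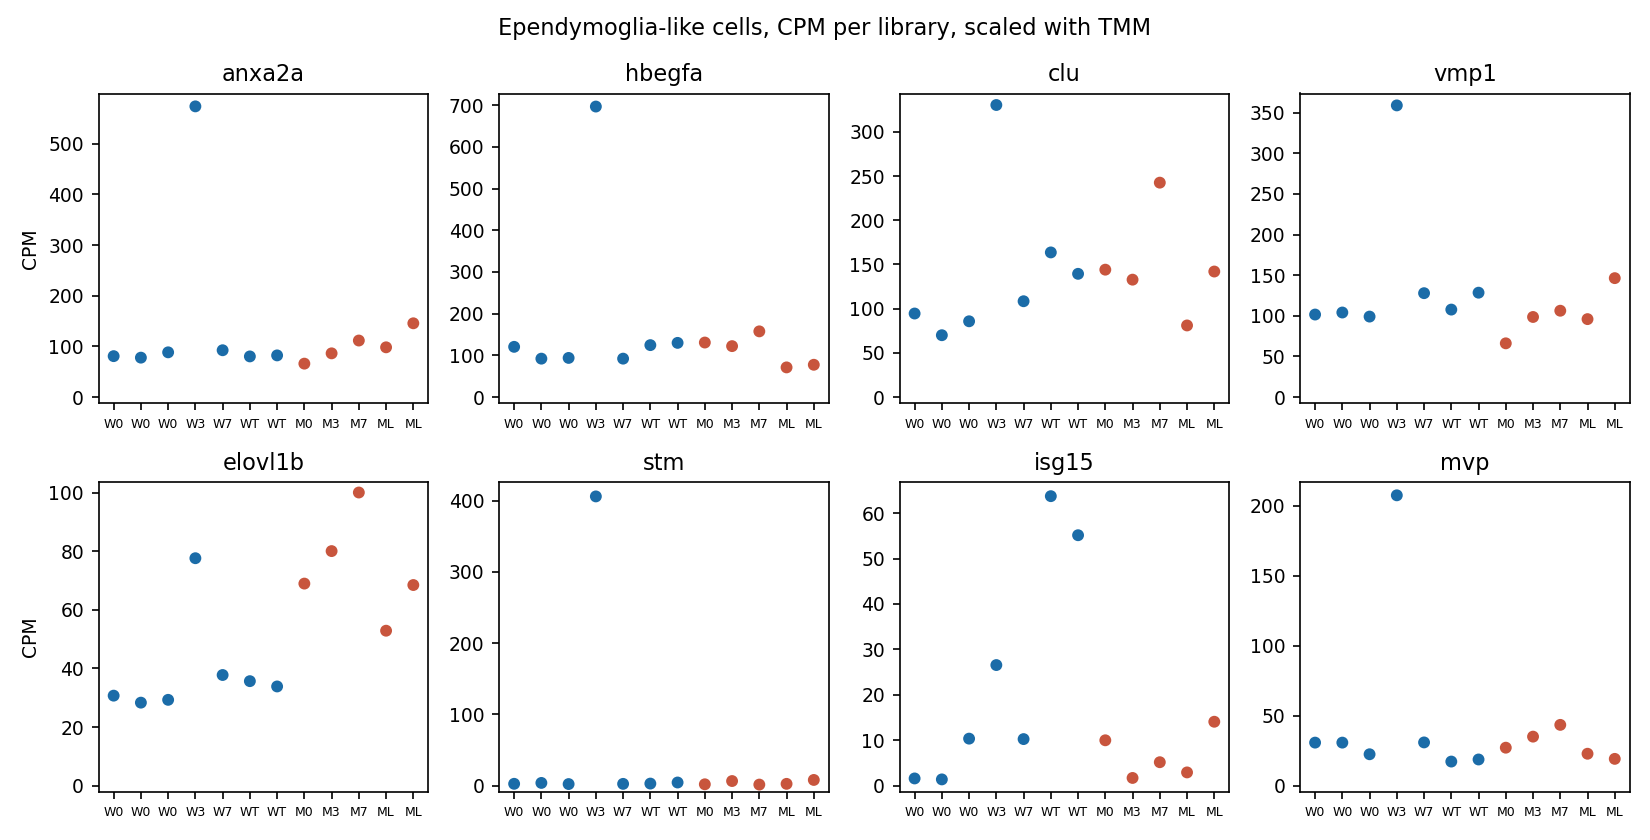
CPM scaled with TMM (y axis) of 8 genes in the summed ependymoglia-like cells of each library (x axis: W wildtype in blue, M mutant in red; 0 intact, 3 and 7 dpi, T cleaved TDP-43, L lipoamide; 1 point per library). anxa2a and hbegfa reach 574 and 697 in wildtype at 3 dpi and lie at 86.3 and 122 in the mutant at 3 dpi.

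Oligodendrocyte progenitor (OPC)-like cells at 3 dpi raised mmp9, a matrix protease gene (301 UMIs against 1, interval of the ratio 45.6 to 10100, adjusted p = 0.00295, edgeR), and lin28a, an RNA-binding gene of stem cells (185 against 1, interval of the ratio 27.9 to 6250, adjusted p = 0.00295). They also raised clcf1, a cytokine gene (at least 30.4-fold, adjusted p = 0.0335), and ccn1, a matrix signalling gene (3.26 ± 0.46, adjusted p = 0.00770). The phosphatidylserine receptor gene timd4 fell to −2.90 ± 0.48 (adjusted p = 0.0370), and akr1a1a was at least 36.4-fold lower (adjusted p = 0.0370). That made 4 genes higher and 2 lower (416 at an unadjusted p under 0.05, DESeq2 called 0). At 7 dpi 0 passed by edgeR (219 at an unadjusted p under 0.05, DESeq2 called 0). The 6 became 113 and 0 without wildtype intact replicate 1 or 2 and 2 without either TDP-43 replicate. The 0 at 7 dpi became 68 without wildtype intact replicate 1.

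Neuron-like cells had 0 genes past the threshold at 3 dpi by edgeR (777 at an unadjusted p under 0.05, DESeq2 called 19). At 7 dpi the neuropeptide gene npffl (ENSDARG00000045016) rose by 9.87 ± 0.28 (adjusted p = 3.26e-05), with 3016 UMIs (217 CPM) in the 1 wildtype 7 dpi library. The Wnt inhibitor gene dkk1b fell to −4.23 ± 0.26 (adjusted p = 0.00416) and gpr78b was at least 135-fold lower (adjusted p = 0.00710; 927 genes at an unadjusted p under 0.05, DESeq2 called 80). Both mark a cluster with dkk1b, gpr78b and kiss1 among its leading genes that held 1.33, 3.54 and 4.46% of cells in the wildtype intact libraries and 0 of 13574 cells at 7 dpi, which allows up to 0.0221%. Without wildtype intact replicate 1 the counts were 905 at 3 dpi and 844 at 7 dpi. The intact libraries left in those fits lay in other library sets than the injured ones, so the counts mix injury with library set. The 3 calls at 7 dpi became 29 without replicate 3 and 31 and 29 without lipoamide replicate 1 or 2.

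The genotypes differed in many genes of these 3 classes over the 3 times. In ependymoglia-like cells grna stood at −4.10 ± 0.53 (3 UMIs against 55, interval of the ratio 0.00980 to 0.151, 3 libraries per genotype, adjusted p = 0.00833, edgeR) and grnb fell to −2.99 ± 0.23 (adjusted p = 0.00138). her12, a Notch target gene, rose by 3.75 ± 0.13, vamp1 by 1.38 ± 0.15 and krt18a.1 by 1.32 ± 0.22. loxl2b (−4.58 ± 0.18), the fatty acid thiolase gene acaa1 (−4.38 ± 0.17) and glb1l (−3.27 ± 0.23) fell. In OPC-like cells mhc1zba rose by 4.13 ± 0.20, the respiratory chain gene cox4i2 by 2.07 ± 0.13 and ccdc80 by 1.76 ± 0.23. There grnb fell to −2.68 ± 0.43 (adjusted p = 0.00182), sdr16c5b to −2.03 ± 0.19, the glial transcription factor gene sox8b to −1.99 ± 0.21 and glrx to −1.81 ± 0.20. In neuron-like cells mia2 rose by 1.19 ± 0.10 and olig2 by 1.07 ± 0.16, and grnb (−2.42 ± 0.19), the proteasome subunit gene psmd10 (−2.18 ± 0.23), bzw1b (−1.66 ± 0.10) and the neuropeptide gene pyyb (−1.40 ± 0.25) fell. Across the 3 classes hbaa1 stood higher by 2.54 ± 0.20, 2.60 ± 0.14 and 2.80 ± 0.14, as it did in microglia-like cells, and how much of it was free RNA from erythrocytes was not tested. ndufb3, a subunit gene of respiratory complex I, fell to −1.92 ± 0.13, −1.79 ± 0.15 and −1.82 ± 0.09, in the order in which the classes were named. The counts were 364 higher and 370 lower in ependymoglia-like cells (3031 at an unadjusted p under 0.05, DESeq2 called 632). They were 159 and 170 in OPC-like cells (1508, DESeq2 called 91), and 463 and 397 in neuron-like cells (3295, DESeq2 called 685). Without the intact pair they were 339 in ependymoglia-like and 147 in OPC-like cells. Without the 3 dpi pair they were 192 in OPC-like and 544 in neuron-like cells, and without the 7 dpi pair 581 in OPC-like and 146 in neuron-like cells.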

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

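The tests of the difference in injury at 3 dpi, the splits of the libraries, the tests of the genes between genotypes and the test of free RNA were chosen only after the result was seen, as was the comparison of f13a1a.1 with neuron-like cells.

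The interaction of injury at 7 dpi with genotype passed camera in several groups of microglial genes at the preset correlation only, and in none with an estimated correlation. Its wildtype baseline mixed library sets and its mutant baseline did not, so genotype and library set cannot be told apart in it. Inflammatory genes (adjusted p = 5.43e-06), cell cycle genes (adjusted p = 1.82e-13), iron and heme genes (adjusted p = 0.000576), lysosomal genes (adjusted p = 0.0183), ribosomal protein genes (adjusted p = 0.000576) and microglia markers (adjusted p = 0.00186) lay on the side of a higher effect in the mutant. Oligodendrocyte markers (adjusted p = 0.0119) and neuron markers (adjusted p = 3.31e-09) lay on the other side. With an estimated correlation these became, in the same order, adjusted p = 0.306, 0.479, 0.367, 0.637, 0.821, 0.637, 0.637 and 0.367, and no single gene passed.

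The interaction of injury at 3 dpi with genotype passed for 12 genes in the sums of 4 classes. Here too the wildtype baseline mixed library sets. The antiviral modifier gene isg15 differed by −6.53 in ependymoglia-like cells, the neuropeptide gene kiss1 by −8.09 in OPC-like cells and si:dkey-7i4.24 by −11.32 in microglia-like cells. In neuron-like cells the Wnt inhibitor gene dkk1b differed by −9.68, gpr78b by −6.23, sox12 by −6.13, gulp1b by −4.52, aoc1 by −4.01, FO704871.1 by −3.97, bambia by −3.39, zic5 by −3.26 and inhbab by −3.20. DESeq2 called 0 genes in microglia-like and in OPC-like cells, 12 in ependymoglia-like and 54 in neuron-like cells. With no read layout covariate the counts were 0 in microglia-like, 1 in OPC-like, 0 in ependymoglia-like and 4 in neuron-like cells. Without wildtype intact replicate 1 they were 10 in OPC-like, 0 in ependymoglia-like and 160 in neuron-like cells, without replicate 2 there were 8 in ependymoglia-like cells, and without replicate 3 there were 0 in ependymoglia-like and 25 in neuron-like cells. dkk1b, gpr78b, sox12, aoc1, FO704871.1 and kiss1 mark a cluster that held 4.90% of the intact mutant library and 0 of 15318 cells of the mutant 3 dpi library, which allows up to 0.0196%, against 1.33% of wildtype intact replicate 1 and 1.81% of the wildtype 3 dpi library. In neuron-like cells kiss1 stood at 257 and 431 CPM in wildtype intact replicate 1 and at 3 dpi, and at 2161 and 0.988 CPM in the mutant. In OPC-like cells these were 9.01, 57.1, 63.4 and 1.72 CPM, and whether they were free RNA from that cluster was not tested. How much tissue near the habenula each dissection took in was not recorded.

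A cluster with genes of both microglia and oligodendrocytes held 95 cells, all from the mutant 3 dpi library (0.620% of its cells, exact interval 0.502 to 0.758%). It was in no class of the report and is listed as a signal in data that the comparisons leave out.

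The first pattern weighed was the set of 98 genes between genotypes in microglia-like cells. Of those measured in neuron-like cells 81.0% (64 of 79) had the same sign there, against 61.6% of all genes, which fits a difference in the genetic background of the lines. Both classes came from the same libraries, so any other difference shared by whole libraries would give the same sign too. Variation linked to the mutated genes stays open: genes called in any class were 1.38 times as frequent near grna and grnb (both left out) as tested genes were, and only 79.7% of the called genes had a place in the annotation at hand. Among the genes with UMIs in the later libraries, 82.8% (77 of 93) had the same direction between mutant and wildtype there, against 54.3% of all genes. Most of these genes thus kept their direction in other libraries. The labels do not say whether the later fish came from another cohort, and the later groups differed in treatment as well as genotype. The cohort of mutant fish therefore stays open. Genes at 0 UMIs in both later groups were not counted. All of those, mhc2b among them, had been higher in the earlier mutant libraries and did not recur. Loss of progranulin itself is the biological explanation and cannot be told apart from the background, because the labels do not say whether mutants and wildtype fish were siblings.

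Other splits of the 6 libraries were counted for the same comparison. As many genes came in 1 of 10 splits in each class, the real one: 98 against at most 3 in microglia-like, 329 against 0 in OPC-like, 734 against 0 in ependymoglia-like and 860 against at most 1 in neuron-like cells. The 10 splits are too few for a share under 0.05. In the other splits the genotype difference stays in the residual spread, so few calls there follow from any strong difference between the genotypes, whatever its cause. The 3 and the 1 came from splits that tested more genes than the real one (9361 against 8016, and 16925 against 16151).

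The second pattern was the oligodendrocyte transcripts in wildtype 3 dpi microglia-like cells. Free RNA from other cells was argued against, since the markers' median log2 ratio to intact replicate 1 was −0.332 in neuron-like cells and 2.08 in microglia-like cells. Doublets stay open. Without the highest doublet scores the median log2 fold change was 2.67, but against all intact libraries together. Replicates 2 and 3 of these held 11.8 and 25.3 CPM of the markers, against 131 in replicate 1. In neuron-like cells they were lower too, at 42.0 and 55.8 against 180.5 CPM. The scores also came from a caller that did not find the doublets that loading would give. For the lower level of the markers in the mutant, cluster naming stays open. With the mixed cluster added, the median log2 difference at 3 dpi became 1.52. That cluster was set aside because it carries genes of both cell types, so adding it had to raise the markers and decides nothing. Uptake of myelin debris by microglia is a biological explanation that was not tested.

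The third pattern was f13a1a.1, with over 100 UMIs in 4 libraries and 1 UMI in lipoamide replicate 2. A few cells of another type stay open: 2.04% of the wildtype 7 dpi microglia-like cells had a UMI of it (exact interval 0.559 to 5.14%), as did 1.55% of the shallower neuron-like cells, and although 1388 of 2043 UMIs lay in 1 cell, the type of that cell was not tested. Reads shared with a paralog were argued against, with a median of 13.3 CPM of f13a1b in the 8 other libraries. A variant carried by some of the pooled animals stays open. After thinning, the share of cells with a UMI ran from 1.38 to 4.17% in the 4 libraries. That lies under the range predicted for such a variant and also far from the one predicted without it, so the test does not decide. No biological explanation was tested.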

How the results depend on the processing

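The tests without the highest doublet scores, with the mixed cluster, without the 2 libraries with the fewest microglia-like cells, and of time over both genotypes were chosen only after the result was seen. All 72 alternative values for the targeted genes counted as the same as in the main run, which does not test a direction between genotypes. Of 381 counts of genes 147 moved, of 146 counts of lists 31, of 60 shares 8 and of 57 correlations 31. Of 2702 values for named genes 2406 stayed the same, 83 were stronger, 212 weaker and 1 reversed, and of 1206 for single lists 947 stayed the same, 251 were weaker and 8 reversed. Where no reason is given below, the cause was not tested. Fits without wildtype intact replicate 1 compare injured with intact wildtype between library sets, so their counts mix injury with library set.

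Counts of genes follow for microglia-like cells unless another class is named. The DESeq2 Wald test gave 15 for wildtype 3 dpi, 3 for wildtype 7 dpi, 12, 5 and 11 for genotype in intact, 3 dpi and 7 dpi brains and 5 for lipoamide; 0 for OPC-like cells at 3 dpi and 91 for genotype; 70 and 9 for ependymoglia-like and 19 and 80 for neuron-like cells at 3 and 7 dpi; and correlations of 0.338 and −0.161. With no filter on low counts, which tests more genes, the counts were 71 and 19 for wildtype and 9 and 10 for mutant injury, 38, 66 and 49 for genotype, 9 for the interaction, 58 for lipoamide, 64 for TDP-43 and 346 over 3 times; 45, 16 and 585 in OPC-like cells at 3 dpi, 7 dpi and between genotypes; 10 in ependymoglia-like cells at 3 dpi; and correlations of 0.315, −0.268 and −0.024.

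With no read layout covariate they were 4 and 2 for wildtype injury, 5 for genotype at 3 dpi, 0 for lipoamide and 2 for TDP-43, 3 in OPC-like cells at 3 dpi and 1 in neuron-like cells at 7 dpi; 4, 9 and 11 lists passed for genotype intact, lipoamide and TDP-43; and the correlations were 0.463, −0.119 and −0.184. With library set as covariate they were 14 for wildtype 3 dpi, 12, 29 and 32 for genotype, 7 for lipoamide and 21 for TDP-43; 11 and 1 in OPC-like and 12 and 38 in neuron-like cells at 3 and 7 dpi; and correlations of 0.218, −0.12 and −0.094. The replicate block gave 17 and 3 for wildtype injury, 16, 32 and 29 for genotype, 19 for lipoamide, 90 for TDP-43 and a correlation of 0.434. For the interaction at 3 dpi it gave 1, 1, 0 and 6 in microglia-like, OPC-like, ependymoglia-like and neuron-like cells. The numbers do not pair the samples: deviations of same-numbered libraries correlated at 0.088, 0.135 and 0.109. The mean of 3 differences in the 12-library fit gave 41, 91 and 308 for genotype in microglia-like, OPC-like and neuron-like cells.

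Strict cells gave 0 for mutant 3 dpi and for lipoamide, 3 in OPC-like cells at 3 dpi, shares of 1.12% in wildtype intact replicate 1, 2.54% and 2.75% in wildtype and mutant at 3 dpi and 2.90% in mutant 7 dpi, 6, 3 and 8 lists for wildtype 7 dpi, TDP-43 and genotype over 3 times, and correlations of 0.195, −0.125 and −0.11. With the highest doublet scores out there were 0 for wildtype 7 dpi, mutant 3 dpi and lipoamide, 2 for genotype at 7 dpi, 2 in OPC-like and 46 in ependymoglia-like cells at 3 dpi, shares of 1.73%, 1.21% and 1.87% in wildtype 3 dpi, wildtype 7 dpi and mutant 7 dpi, 3 and 2 lists for wildtype 7 dpi and TDP-43, and correlations of 0.249 and −0.09. The mixed cluster gave 65 genes and 3 lists over 3 times and a share of 2.66% in mutant 3 dpi. Without the 2 libraries with the fewest microglia-like cells there were 12 for wildtype 3 dpi, 0 for lipoamide, 3 for TDP-43, 6 in ependymoglia-like cells at 3 dpi, 29 in neuron-like cells at 7 dpi, and correlations of 0.464 and −0.125. Resolution 2 gave 2 in OPC-like cells at 3 dpi and a correlation of −0.066, doublets kept 48 in ependymoglia-like cells at 3 dpi, and time over both genotypes 1 at 3 dpi. With an estimated correlation 0 lists passed in every comparison.

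With single libraries left out, counts ran from 6 to 28 and from 1 to 16 for wildtype 3 and 7 dpi, 6 to 20, 12 to 26 and 5 to 24 for genotype, 0 to 4 for the interaction, 0 to 22 for lipoamide, 0 to 12 for TDP-43 and 31 to 151 over 3 times. OPC-like cells ran from 0 to 113, 0 to 68 and 147 to 581, ependymoglia-like from 6 to 239, 0 to 131 and 339 to 877, and neuron-like from 0 to 905, 3 to 844 and 146 to 1089, for 3 dpi, 7 dpi and genotype. Lists ran from 7 to 12 and 3 to 13 for wildtype 3 and 7 dpi, 5 to 10 for genotype at 3 dpi, 5 to 13 for the interaction, 2 to 6 for lipoamide and 3 to 7 for TDP-43, and correlations from 0.192 to 0.297, −0.159 to −0.05 and −0.153 to −0.03.

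Reversed results were few. For antigen presentation, wildtype 3 dpi against intact, the test pointed down without wildtype intact replicate 1 (adjusted p = 0.982) and up without replicate 2 (adjusted p = 0.00105). For ependymoglia markers, wildtype 7 dpi against intact, it pointed down without the highest doublet scores (adjusted p = 0.170) and without replicate 2 (adjusted p = 0.194), and up without replicate 1 (adjusted p = 1.49e-12). The same markers reversed without the highest doublet scores at mutant 3 dpi (adjusted p = 0.303) and between genotypes at 3 dpi (adjusted p = 0.229), and for TDP-43 with no read layout covariate (adjusted p = 0.849). For oligodendrocyte markers, mutant against wildtype 3 dpi, the mixed cluster turned the test up (adjusted p = 8.09e-06), as it did over 3 times (adjusted p = 0.665), since that cluster carries them. For tardbp in microglia-like cells, mutant against wildtype over 3 times, the log2 difference was −0.017 without the 3 dpi pair and 0.277 without the intact pair. Microglia-like sums rested on 22 to 312 cells per library, which limits what the lipoamide comparison can find.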

Other observations

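The 3 dpi tests of the mutant below were chosen only after the result was seen, and their genes were picked in the wildtype library, which favours a smaller effect in the mutant.

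The 21 genes called in wildtype ependymoglia-like cells at 3 dpi were read in the mutant cells as well. hbegfa, a growth factor of the EGF family that drives glia into regeneration in the fish retina, stood at 2.73 in wildtype and −0.11 in the mutant, a difference of −2.84 ± 0.30 (adjusted p = 0.0614 over all genes). anxa2a, a membrane-binding annexin, stood at 2.89 and 0.38 (difference −2.52 ± 0.28, adjusted p = 0.0614), and the extracellular chaperone gene clu at 2.08 and −0.13. The interferon-induced gene isg15 stood at 3.97 ± 0.28 and −2.56 ± 0.39, and its difference passed (−6.53 ± 0.49, adjusted p = 0.0174). Over the 21 genes the median was 2.66 in wildtype and 0.21 in the mutant, and 13 had the same direction. Tested over all genes, 1 difference passed (432 at an unadjusted p under 0.05; DESeq2 called 12). In the mutant 0 genes passed at 3 dpi by edgeR (575 at an unadjusted p under 0.05; DESeq2 called 0). Each genotype had 1 library at 3 dpi, and the count of 1 became 0, 8 and 0 without wildtype intact replicate 1, 2 or 3, and 0 with no read layout covariate.

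In OPC-like cells 4 of the 6 genes called in wildtype at 3 dpi had the same direction in the mutant, and 0 of their differences passed over all genes. In microglia-like cells 1 difference of the 7 genes passed over all genes.

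Averaged over both genotypes, anxa1a, an annexin of the resolution of inflammation, rose in microglia-like cells at 3 dpi by 4.80 ± 0.52 (2 libraries per time; adjusted p = 0.0244; 605 genes at an unadjusted p under 0.05), and rbp4, which carries retinol, was the 1 gene that fell at 7 dpi (360 at an unadjusted p under 0.05).

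A cluster of photoreceptor or pineal type held 0.911% of the cells of wildtype intact replicate 1 and 1.68% of those of replicate 3.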
